A study of Mus musculus with 2 samples.

How the data were processed

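RNA was measured in 2 libraries of mouse fallopian tube (oviduct) epithelial organoids, 1 control library and 1 Trp53 knockout library. The groups were taken from the submitters' genotype labels. Both libraries carried the same treatment label, conditioned medium, so the treatment was not compared. Total RNA was isolated with an RNeasy Plus kit, strand-preserving libraries were made with a NEBNext Ultra II Directional kit, and paired-end reads were sequenced on a NextSeq2000, per the labels' protocols. The genome build was GRCm39, per the submitters' processing notes. The aligner, the counting tool, the strand setting of the counting and the gene annotation are not given in the sources used here.

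The authors deposited TPM (length-scaled transcript abundance, reads divided by gene length and scaled to the same total in each library) for 25668 gene symbols per library. TPM keeps no depth by itself. Whether whole reads had been counted was checked on the ratios between the libraries of low values. Of 1676 genes above 0 and below 0.5 TPM in both libraries, 75.6% had a ratio within 0.001% of 1 constant times a fraction with a denominator of at most 12. With 200 arbitrary constants from 0.5 to 2 times as large, the median share was 0.805% and the highest 16.2%. At a tolerance of 0.1% the shares were 90.9% and, for the median arbitrary constant, 44.1%, so the tighter tolerance, chosen after this was seen, was used. The reads per TPM were then taken from genes whose length equals that of their longest protein-coding transcript in GENCODE M21. With that length, 5945 of 16128 genes had read numbers within 0.02 of a whole number in both libraries, where a listed 0 counts as whole. Among 10239 genes with over 50 reads in both libraries the share was 30.9%, against 0.16% by chance. The 1287 genes that set the reads per TPM were not left out, so the check is partly circular. For all other genes the read numbers are estimates that assume this length. This step was chosen after the data were examined. GENCODE M21 belongs to an earlier genome build than the deposited values, so it was used for gene names, chromosome membership, gene type, transcript length and sequence composition, and no coordinates are given.

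The recovered and estimated reads summed to 100209452 in the control library and 27720209 in the knockout library. At a gene length of 1000 bases, 1 read was worth 0.0168 TPM in the control library and 0.0565 TPM in the knockout library. Intervals on a ratio of TPM are exact Clopper-Pearson intervals at 95% from these reads. Where a library lists a gene at 0 TPM, a floor of 3 reads in that library gives the bound on the fold. This bound is less strict than the 95% interval, which for Lyz2 began at 1622-fold, against 1994-fold from the floor. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

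Differences are log2(TPM + 1) in the knockout library minus log2(TPM + 1) in the control library, for genes with a mean TPM of at least 1. The pseudocount of 1 makes these differences smaller than the TPM ratio for low genes. Genes were counted as higher or lower at a difference of at least 2-fold on this scale. With 1 library in each group no test between genotypes was possible. No p-value or SD is given, and a difference compares these 2 libraries.

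Before the data were examined, 39 gene lists were fixed, 8 of them with markers of other cell types. A list with at least 5 measured members was described by the percentile of its median among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. A median below the 2.5th or above the 97.5th percentile is said to lie outside the random range. The same was done for the genes of each of 20 chromosomes. Named genes are Trp53, the 10 highest and 10 lowest differences among genes with a mean TPM of at least 5, and up to 4 members of each list with the largest differences in either direction. Predicted genes, unnamed clones, pseudogenes, mitochondrially encoded genes and ribosomal protein genes were left out of the 10 highest and lowest. A few genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

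The alternatives were a pseudocount of 0.1 or 5, no filter on low values or a mean TPM of at least 5, rescaling by the median ratio, quantile normalization, removal of mitochondrially encoded genes and the 100 highest genes, protein-coding genes only, a 4-fold threshold and random lists not matched on expression. Thinning of the control reads to the knockout depth and leaving out the genes on chromosomes 2 and 4 were added after the data were examined.

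The gene counts and list percentiles were tested on simulated reads of 24932 genes at the depths of both libraries. All 96 measured genes with a simulated 4-fold change were recovered (100%), and 0 unchanged genes were called among 11118 measured. Of 200 simulated lists of 25 unchanged genes, 5.5% lay outside the range of 2000 random lists, and 100% of 50 lists raised 1.4-fold lay above it. The unchanged lists were drawn at random from the same genes as the random lists, so their share outside the range was set by the design. The simulation held counting error only, so the result for raised lists may not hold for the wider real differences. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.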

Results

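Organoids of fallopian tube epithelium, the secretory and multiciliated cell layer of the oviduct, were grown from a mouse line carrying a Cas9-EGFP transgene, and Trp53, which encodes the tumour suppressor p53, was knocked out. The data are 1 control library and 1 Trp53 knockout library, each with TPM values for 25668 genes. TPM was above 0 for 16094 genes in the control library and 14066 genes in the knockout library, and the recovered and estimated reads together summed to 100209452 and 27720209. The comparison asks what loss of Trp53 function does to gene expression in this epithelium. None of the differences has a replicate check.

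Trp53 stood at 83.2 TPM in the control library and 2.42 TPM in the knockout library, a ratio of 0.0291 with a counting interval of 0.0231 to 0.0363. Of 11228 genes measured, 937 (8.35%) were at least 2-fold higher and 1715 (15.3%) at least 2-fold lower in the knockout library. The counting interval of the TPM ratio, taken without the pseudocount, lay wholly beyond 2-fold for 870 of the higher and 1599 of the lower genes. An interval was available for 11019 of the 11228 genes, and genes without one are not in these 2 counts. The median difference over all genes was −0.17, and quantile normalization moved it to 0.03 and the split to 1292 higher and 1321 lower genes. Rescaling by the median ratio gave 1191 higher and 1461 lower genes. Spearman's correlation across genes, which are not independent replicates, was 0.844.

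**Figure D1:**
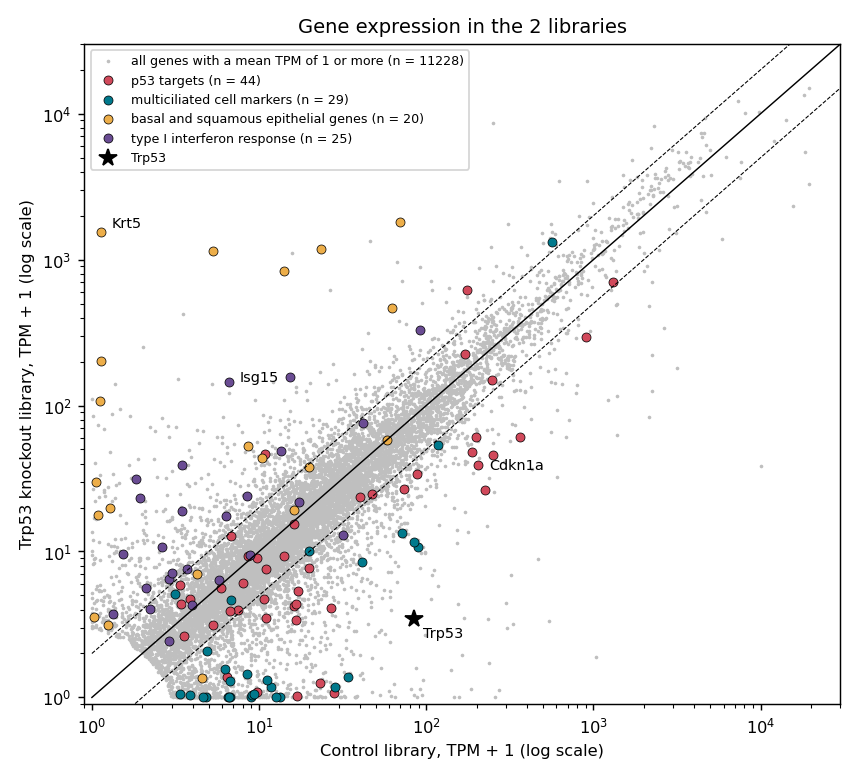
Each point is 1 gene, with TPM + 1 in the control library on the x axis and in the Trp53 knockout library on the y axis, both on log scales; the solid line marks equal values and the dashed lines a 2-fold difference. Members of 4 gene lists are coloured, and Trp53 (star) lies at 83.2 and 2.42 TPM.

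Genes that p53 activates were lower in the knockout library as a group. Of 44 measured p53 targets, 22 were at least 2-fold lower and 2 at least 2-fold higher, and the list median of −1.05 lay at percentile 0 of the random lists. Kitl, which encodes the ligand of the receptor Kit, was 27.2 TPM in the control and 0.0686 TPM in the knockout library. Dglucy, an enzyme of glutamate metabolism, was 22.2 and 0.249 TPM, and Eda2r, a receptor of the tumour necrosis factor family, was 8.69 and 0.0943 TPM. Sulf2, an extracellular sulfatase, had 15.9 and 0.0218 TPM, the latter from an estimated 2 reads, for a ratio of 0.00137 with a counting interval of 0.000188 to 0.00562. Among members chosen after their values were seen, Cdkn1a, the cyclin-dependent kinase inhibitor p21, was 203.0 and 38.1 TPM, and Mdm2, the ubiquitin ligase that degrades p53, was 46.6 and 23.9 TPM. Phlda3, also chosen afterwards, was 169 TPM in the control and 225 TPM in the knockout library, and the 2 higher members, Perp and Sytl1, were 175 and 9.81 TPM in the control and 616 and 45.7 TPM in the knockout library. Of 11 members of the p53 family and regulators list, 3 were higher and 1 lower, with a median of 0.33 at percentile 97.7. Trp63, the p53 relative that maintains basal cells, was 0.0280 TPM in the control and 16.0 TPM in the knockout library. Cdkn2a and Cdkn2b, neighbouring cell cycle inhibitor genes on chromosome 4, were 74.6 and 19.1 TPM in the control and 361 and 58.1 TPM in the knockout library. Hipk2, a kinase that phosphorylates p53, was 2.97 and 0.643 TPM. The percentile of this list fell inside the random range under 6 alternatives.

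Keratins and other genes of basal and squamous epithelium were far higher in the knockout library. Of 20 measured members 15 were at least 2-fold higher and 1 lower, and the median difference of 3.43 lay at percentile 100. It was 2.35 with no filter on low values and 2.18 with a pseudocount of 5, both still at percentile 100. Krt5, a keratin of basal cells, was 0.130 TPM in the control and 1543 TPM in the knockout library, and its basal partner Krt14 was 0.129 and 200.4 TPM. Krt13, a keratin of non-cornified squamous epithelium, was 4.29 and 1140 TPM, a ratio of 265.9 with a counting interval of 242 to 293. Krt6a, an inducible keratin, was 0.125 and 106 TPM. The 1 lower member, chosen after its values were seen, was Lor, loricrin, at 3.54 and 0.350 TPM. Krt6a and Krt14 have close paralogs with which reads can be shared, so their single values are uncertain. The 10 highest differences also held Pitx1, a homeobox factor (0.0190 and 83.4 TPM), Tpm2, a tropomyosin (1.03 and 248.9 TPM, on chromosome 4), Sncg, gamma-synuclein (0.375 and 139 TPM), Upk3bl, an uroplakin relative (2.49 and 422 TPM), and S100a14, a calcium-binding protein of epithelia (14.7 and 1112 TPM). Pitx1 had an estimated 3 reads in the control library, and its ratio interval ran from 1386 to 19667. Lypd2 was listed at 0 in the control library and at 111 TPM in the knockout library, at least 1126-fold higher.

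The multiciliated program was lower in the knockout library. Of 29 measured multiciliated cell markers 25 were at least 2-fold lower and 1 higher, with a median of −2.55 at percentile 0. In the knockout library 8 members were listed at 0. With every value below 3 reads raised to that floor, the median log2 ratio without a pseudocount was −4.62. The median difference was smaller in size with no filter on low values (−1.40) and with a pseudocount of 5 (−1.09), both still at percentile 0. Mlf1 was 33.3 and 0.372 TPM, and Ccno, a cyclin-like protein needed for centriole amplification, was 27.4 and 0.181 TPM. Tppp3, a microtubule-bundling protein, was 12.3 TPM in the control library and listed at 0 in the knockout library, at least 101-fold lower, and Ccdc153, an axonemal protein, was at least 74.5-fold lower. The 1 higher member, chosen after its values were seen, was the tubulin gene Tubb4b at 567 and 1325 TPM. Of 22 secretory cell markers 5 were higher and 7 lower, and their median of −0.05 lay at percentile 27.7, inside the random range. Ovgp1, the oviduct glycoprotein, was 7.44 and 0.192 TPM, Lcn2, lipocalin 2, was 15660 and 2342 TPM, Wt1, a transcription factor, was 35.3 and 7.85 TPM, and Sprr2f, a small proline-rich protein, was 22.3 and 168 TPM. Pax8, the transcription factor of secretory cells, chosen after its values were seen, was 44.8 TPM in the control library and 46.0 TPM in the knockout library.

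Of 14 measured mucins and secreted oviduct proteins 9 were lower and 4 higher, with a median of −1.96 at percentile 0. The median log2 ratio was −2.03 with values below the floor raised to it. Pigr, which carries immunoglobulins across epithelium, was 556 and 64.6 TPM, and Scgb3a1, a secretoglobin, was 235.6 and 30.6 TPM. Tff1, a trefoil peptide, was listed at 0 in the control library and at 9.09 TPM in the knockout library, at least 127-fold higher, and Adm2, a peptide hormone, was 3.12 and 28.3 TPM. Sex steroid receptors and hormone-responsive genes had 5 of 11 members lower and 2 higher, with a median of −0.96 at percentile 0.58. The median log2 ratio of this list was −0.99 with values below the floor raised to it. With no filter on low values the median was −0.27, inside the random range. Igfbp4, which binds insulin-like growth factors, was 140 and 0.548 TPM, C3, complement component 3, was 2231 and 124 TPM, and Areg, an EGF receptor ligand, was 0.802 and 7.03 TPM.

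Genes of NF-kB signalling and chemokines were lower as a group. Of 31 NF-kB and chemokine genes 13 were lower and 5 higher, with a median of −0.73 at percentile 0. Ccl2, the chemokine that attracts monocytes, was 1030 TPM in the control and 0.904 TPM in the knockout library, a control to knockout ratio of 1140 with a counting interval of 666 to 2140. Saa3, serum amyloid A3, was 270.4 and 0.130 TPM, and Ccl28, a mucosal chemokine, was 320.5 and 5.91 TPM. Ccl7, with 2 recovered reads in the knockout library, had a control to knockout ratio of 566 and an interval of 157 to 4675. The 5 higher members, chosen after their values were seen, were Il1a (1.08 and 21.3 TPM), Cxcl3 (15.7 and 123 TPM), Ptgs2 (11.7 and 43.4 TPM), Il33 (49.8 and 114 TPM) and Csf2 (14.9 and 34.2 TPM). The other lowest differences were Hp, haptoglobin (10040 and 37.7 TPM), Cyba, a subunit of NADPH oxidase (541 and 2.36 TPM), Cyp2f2, a cytochrome P450 (327 and 2.18 TPM), Bex1 (237 and 0.718 TPM) and Pcp4l1 (184 and 0.143 TPM). Lyz2 and Lyz1, paralogous lysozymes that can share reads, were 257 and 155 TPM in the control library and listed at 0 in the knockout library, at least 1994-fold and 1154-fold lower. Dcaf12l1 was at least 2992-fold lower from 145 TPM. Lyz2 is also on the list of immune cell markers, of which 2 of 6 measured members were lower and 2 higher. The other lower member was Csf1r, a receptor of macrophages, at 8.78 and 0.420 TPM, and the higher ones were S100a8 (3.53 and 18.5 TPM) and S100a9 (2.83 and 19.9 TPM).

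Interferon-stimulated genes were higher, while antigen presentation genes were lower. Of 25 type I interferon response genes 17 were higher and 1 lower, with a median of 1.46 at percentile 100. Isg15, a ubiquitin-like modifier on chromosome 4, was 5.62 and 144 TPM, Oasl1, of the oligoadenylate synthetase family, 0.830 and 30.3 TPM, Usp18, which removes Isg15 from proteins, 0.941 and 22.2 TPM, and Rtp4 2.44 and 38.1 TPM. The 1 lower member, chosen after its values were seen, was Lgals3bp at 30.8 and 11.97 TPM. Antigen presentation genes had 7 of 17 members lower and 2 higher, with a median of −0.57 at percentile 1.47, and −0.34 inside the random range after quantile normalization. Cd74, the class II invariant chain, was 15.5 and 0.958 TPM, H2-M3 was 13.7 and 1.14 TPM, H2-DMb1 was 4.99 and 0.443 TPM, and Psmb8, an immunoproteasome subunit, was 52.4 and 14.6 TPM. The 2 higher members, also chosen afterwards, were the class I genes H2-K1 (203 and 514 TPM) and H2-T23 (50.3 and 126 TPM). Of the 6 measured immune cell markers, Lyz2 and Csf1r were lower and S100a8 and S100a9 higher in the knockout library. Their median of 0.06 lay at percentile 82.7, inside the random range.

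Genes of the cell cycle were higher in the knockout library. DNA replication and G1/S genes had 13 of 37 members higher and 0 lower, with a median of 0.77 at percentile 100, and G2/M and mitosis genes had 17 of 41 higher and 0 lower, with a median of 0.92 at percentile 100. Pcna, the polymerase clamp, was 249.4 and 714 TPM, Orc1, of the origin recognition complex, 1.07 and 6.73 TPM, Ccne2, cyclin E2, 3.95 and 14.9 TPM, and Gins1, of the replicative helicase, 17.4 and 49.8 TPM. Mybl2, a transcription factor of dividing cells, was 2.40 and 19.3 TPM, Cdca8, borealin, 13.8 and 79.7 TPM, the phosphatase gene Cdc25b 8.43 and 39.2 TPM, and Ube2c, of the anaphase-promoting machinery, 58.8 and 248 TPM. All 8 of these genes lie on chromosome 2 or 4, whose genes were higher as a whole. Of 31 genes of double-strand break and crosslink repair 3 were higher and 1 lower, with a median of 0.24 at percentile 99.8, and 0.21 inside the random range at a mean TPM of at least 5. Rad54l, a motor protein of homologous recombination, was 1.37 and 6.78 TPM, Rad51c 0.697 and 2.66 TPM, and Xrcc5, of the Ku complex, 62.5 and 27.9 TPM. Without the genes of chromosomes 2 and 4, 7 of 30 G1/S genes, 7 of 30 G2/M genes and 1 of 27 repair genes were at least 2-fold higher, and 0, 0 and 1 lower. All 12 lists above the random range were still above it without these chromosomes, and all 7 lists below it were still below it.

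Glucose metabolism and hypoxia genes were higher. Glycolysis genes had 14 of 22 members higher and 2 lower, with a median of 1.33 at percentile 100, and hypoxia response genes had 11 of 20 higher and 0 lower, with a median of 1.12 at percentile 100. Slc16a3, the lactate exporter, was 0.277 and 46.9 TPM, Pfkp, a phosphofructokinase, 2.76 and 38.4 TPM, Pdk1, which inhibits pyruvate dehydrogenase, 6.91 and 65.0 TPM, and Ldhb, a lactate dehydrogenase subunit, 462 and 7.92 TPM. Bnip3, a mitophagy receptor, was 4.26 and 139 TPM, Ankrd37 4.64 and 60.3 TPM, Adm, adrenomedullin, 2.03 and 15.8 TPM, and Ero1a, an oxidase of the endoplasmic reticulum, 16.6 and 76.5 TPM. Cholesterol synthesis and uptake genes had 4 of 25 members higher and 0 lower, with a median of 0.47 at percentile 99.96. The synthesis enzymes Pmvk, Cyp51 and Fdps were 61.4, 142 and 420.2 TPM in the control library and 148, 318 and 865 TPM in the knockout library. The 13 mitochondrially encoded genes were 6 lower and 0 higher, with a median of −0.77 at percentile 0.01, and took 8.72% of TPM in the control and 5.92% in the knockout library. The complex I subunit gene mt-Nd4 was 1372 and 486 TPM. Oxidative phosphorylation genes of the nucleus were 1 higher and 1 lower of 35, with a median of 0.00 at percentile 20.4, Sdhb of complex II on chromosome 4 at 137 and 320.0 TPM and Ndufa1 of complex I at 557 and 269 TPM.

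Ribosomal protein genes had 6 of 43 members higher and 0 lower, with a median of 0.46 at percentile 99.9, and 0.49 inside the random range without the 100 highest genes. Rpl22, Rps20 and Rps6, all on chromosome 4, were 2.74-, 2.69- and 2.65-fold higher. All 6 higher members lie on chromosome 2 or 4. The median was 1.42 over the 5 ribosomal protein genes of chromosome 4. Over the 37 on chromosomes other than 2 and 4 it was 0.44, with 0 at least 2-fold higher and 0 lower. Epithelial-mesenchymal transition genes had 5 of 11 members higher and 4 lower, with a median of 0.66 at percentile 99.8. The median log2 ratio of this list was 0.77 with values below the floor raised to it. With no filter on low values the median was −0.0384, inside the random range. Mmp14, a membrane metalloproteinase, was 3.36 and 54.5 TPM, S100a4 was 5.18 and 37.8 TPM, Itga5, the fibronectin receptor subunit, was 13.9 and 2.09 TPM, and Twist1, a transcription factor, was at least 348-fold lower from 36.3 TPM. Fallopian tube and serous lineage transcription factors were 2 higher and 0 lower of 12, with a median of 0.49 at percentile 99.6, and −0.0140 inside the random range with no filter on low values. Gata3 was 0.396 and 8.86 TPM and Foxa1 0.384 and 5.79 TPM, while Id1 was 38.3 and 76.2 TPM and Gata6 26.1 and 13.7 TPM.

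The other lists had medians inside the random range. Of 26 epithelial junction genes 3 were higher and 1 lower, with Cdh3, P-cadherin, at 0.383 and 22.4 TPM, Ovol1 at 0.862 and 5.38 TPM, Esrp1 at 17.7 and 40.8 TPM and Ovol2 at 6.92 and 2.46 TPM. Of 15 Notch pathway genes 4 were higher and 2 lower, with the Notch ligands Jag2 at 0.178 and 24.4 TPM and Dll1 at 0.848 and 5.69 TPM, Nrarp at 1.75 and 18.5 TPM and Dtx4 at 14.1 and 3.78 TPM. Of 21 Wnt pathway and stem cell genes 4 were higher and 6 lower, with Sp5, a Wnt target, at 37.2 and 1.83 TPM, Sox9 at 12.02 and 1.23 TPM, and the retinal dehydrogenases Aldh1a1 at 10.9 and 0.181 TPM and Aldh1a3 at 1.03 and 12.9 TPM. Of 26 apoptosis genes 3 were higher and 3 lower, with Ripk3, a kinase of necroptosis, at 3.95 and 32.9 TPM, and among the proapoptotic BH3-only genes Bik at 1.80 and 15.1 TPM, Bcl2l11 at 1.52 and 7.16 TPM and Bmf at 7.47 and 1.47 TPM. Fatty acid metabolism had 3 higher and 4 lower of 23, with Fabp5 at 169 and 38.7 TPM and Elovl5 at 115 and 37.7 TPM, and the desaturases Fads2 at 78.7 and 242 TPM and Fads1 at 70.3 and 164 TPM. The unfolded protein and integrated stress response list had 6 higher and 3 lower of 25, with the stress factor Xbp1 at 389.9 and 123 TPM, and the serine and one-carbon enzymes Psat1 at 62.6 and 198 TPM, Mthfd2 at 21.7 and 66.1 TPM and Shmt2 at 42.0 and 118 TPM. NRF2 and glutathione genes had 6 higher and 6 lower of 27, with Nqo1, a quinone reductase, at 0.314 and 7.64 TPM, and the glutathione transferases Gsta1 at 2.27 and 152 TPM, Gstm2 at 1216 and 108 TPM and Gsta3 at 607 and 92.5 TPM. Heat shock genes were 2 higher and 2 lower of 17, with Hspb1 at 70.7 and 712 TPM and Hspa1b at 43.2 and 172 TPM, and with Hspb8 at 10.1 and 0.342 TPM and Cryab at 267 and 63.3 TPM. Immediate early genes were 5 higher and 7 lower of 21, with Ccn2 at 252 and 24.4 TPM, Ccn1 at 644 and 139 TPM, Egr2 at 9.93 and 2.30 TPM and Jun at 18.0 and 124 TPM. Collagens and basement membrane genes were 1 higher and 1 lower of 9, with Lamb1 at 49.7 and 12.4 TPM, Lama3 at 0.374 and 2.09 TPM, Lamb2 at 45.0 and 23.8 TPM and Lamc1 at 13.6 and 8.51 TPM.

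**Figure D2:**
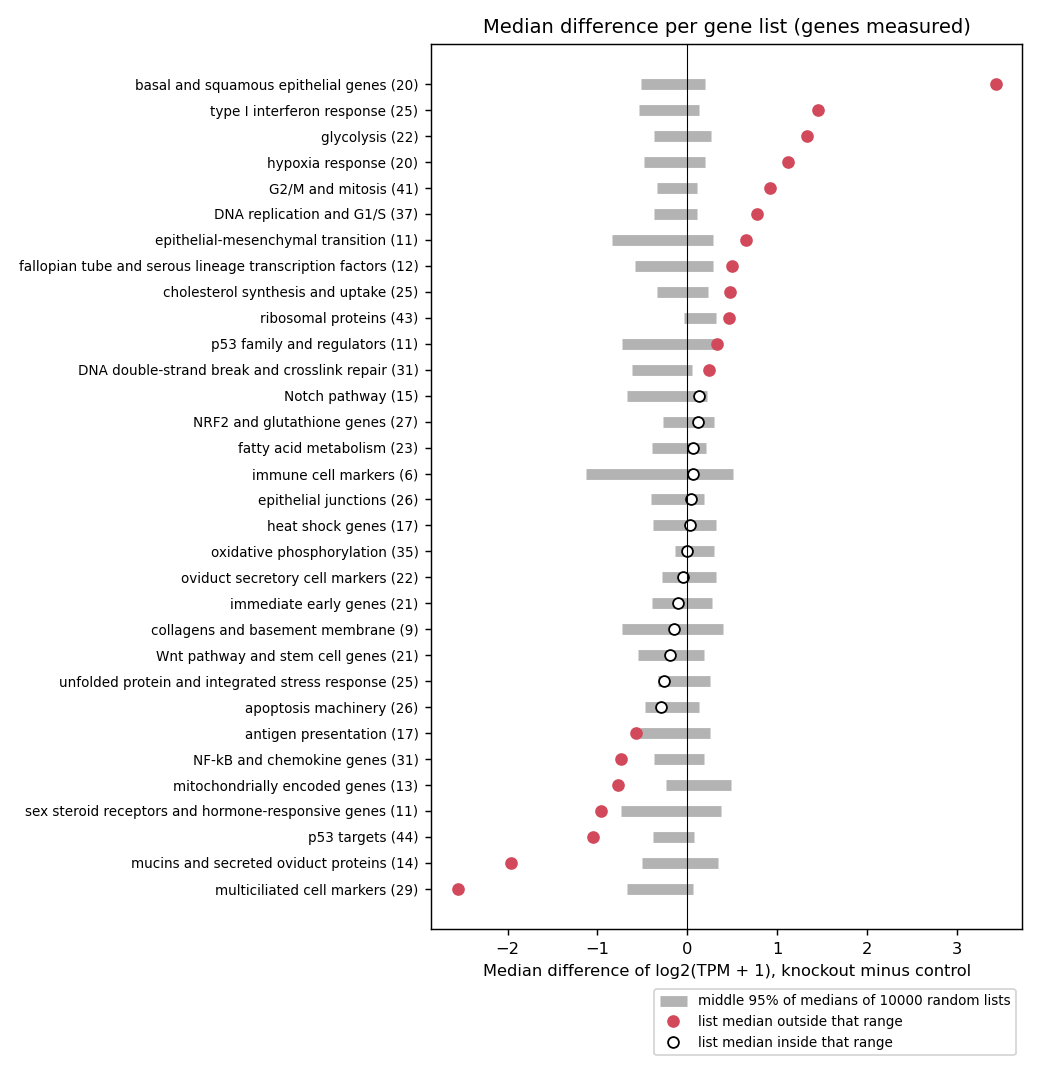
Points are medians of the difference of log2(TPM + 1), knockout minus control, over the measured members of each list (number in brackets), and grey bars span the middle 95% of medians of 10000 random lists matched on expression. The basal and squamous list (3.43) and the multiciliated list (−2.55) lie farthest from 0.

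Genes of chromosome 4 were higher as a whole in the knockout library. Their median difference was 0.63 over 672 genes, at percentile 100 and 0.79 above the median of all genes, a 1.73-fold offset. Chromosome 2 had a median of 0.20 over 895 genes, also at percentile 100, 0.37 above the median of all genes, a 1.29-fold offset. Together the chromosomes held 303 of the genes at least 2-fold higher, 33.4% of those with a known chromosome, against 14.2% of all measured genes with a known chromosome. Chromosome 4 had 196 genes at least 2-fold higher and 43 at least 2-fold lower, while chromosome 2 had 107 higher and 92 lower. The medians of the other 18 chromosomes lay between −0.36 and −0.14, and 8 of them (1, 6, 8, 9, 12, 13, 16 and X) lay below the random range, which was drawn from the genes of all chromosomes.

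**Figure D3:**
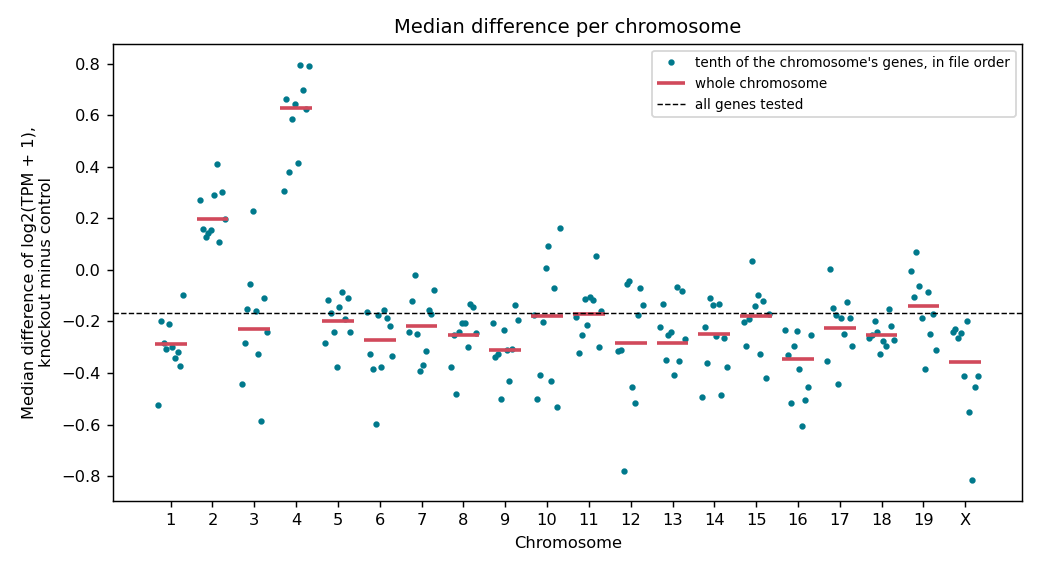
For each chromosome the bar is the median difference of log2(TPM + 1), knockout minus control, over its measured genes, the points are medians of 10 successive equal parts of its genes in the order of the deposited table, and the dashed line is the median of all genes (−0.17). Chromosome 4 (0.63) and chromosome 2 (0.20) lie above the line.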

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

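Thinning of the control reads and leaving out chromosomes 2 and 4 were chosen after the data were examined. No paired analysis was possible because each genotype has 1 library, and no library could be left out for the same reason. No result turned its direction past the threshold. Of 350 list medians under the alternatives, 334 kept their side of the random range, 15 moved inside it and 1 moved outside; of 1488 values of named genes 1459 kept their side of 2-fold, and of 200 chromosome medians 182 kept theirs. Genes at least 2-fold higher numbered 563 and lower 930 with a pseudocount of 5, and 267 and 661 passed 4-fold; lower genes numbered 1091 with a mean TPM of at least 5, where fewer genes are measured. The p53 family median moved inside the random range with a pseudocount of 0.1 (0.35), no filter (0.21), a filter of 5 (0.37), quantile normalization (0.52), thinned reads (0.29) and unmatched lists (0.33). So did antigen presentation with a filter of 5 (−0.50), quantile normalization (−0.34) and unmatched lists (−0.57). With no filter, so did epithelial-mesenchymal transition (−0.0384), sex steroid receptors (−0.27) and lineage transcription factors (−0.0140). With a filter of 5, so did double-strand break repair (0.21) and lineage transcription factors (0.21), and without the highest genes, ribosomal proteins (0.49). The unfolded protein list moved outside the range with quantile normalization (−0.29). The cause was not tested. The medians of 5 lists inside the range changed sign between scalings: secretory markers, oxidative phosphorylation, heat shock, immediate early, and collagens and basement membrane. All 12 lists above and all 7 below the random range kept their side without chromosomes 2 and 4.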

Other observations

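The tests on keratin paralogs and on a single share of multiciliated cells, the thinning of control reads and the genes off in 1 library were chosen after the results they bear on were seen. Ptprc, C1qa, Pdgfra, Tubb4b, Rfx2, Mns1, Cfap45, Foxj1, Mcidas, Gmnc and the Hox genes are also named by choice after their values were seen. Of 4596 genes at 20 TPM or more in the control library, 17 were listed at 0 in the knockout library. Besides Lyz1, Lyz2, Dcaf12l1 and Twist1 they included Pdlim4 at 87.4 TPM, Tceal8 at 63.6 TPM, Snrpn at 36.6 TPM and Sgce at 31.6 TPM, at least 609-, 884-, 448- and 331-fold lower. In the other direction, Lypd2 was the 1 gene of 4293 at 20 TPM or more in the knockout library that was listed at 0 in the control library.

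Markers of other cell types were mostly near 0 in both libraries. Of the immune cell markers 6 were measured, 2 higher and 2 lower, with a median of 0.06 at percentile 82.7. The lower ones were Lyz2, at least 1994-fold lower from 257 TPM, and Csf1r (8.78 and 0.420 TPM), and the higher ones were S100a8 and S100a9. Ptprc, the pan-leukocyte antigen, was 0.0886 and 0.0110 TPM and C1qa was listed at 0 in both libraries. Of the fibroblast and stromal markers 2 were measured, Ly6a (91.2 and 890.3 TPM) and Gsn (278 and 113 TPM), and Pdgfra was 0.0175 TPM and listed at 0. Smooth muscle markers had 3 measured, with Acta2 at 1.07 and 17.8 TPM. Endothelial markers had 2 measured, with Egfl7 at 4.97 and 6.95 TPM, and mesothelial markers had 4 measured, 2 higher and 1 lower, with Pdpn at 14.4 and 91.3 TPM on chromosome 4 and Wt1 at 35.3 and 7.85 TPM. Ovarian granulosa and endometrial markers had 4 measured, 2 higher and 1 lower, with Inhbb at 19.2 and 0.0531 TPM, Sprr2e at 0.389 and 9.09 TPM and Sprr2d at 0.296 and 1.91 TPM. Adipocyte markers had 1 measured, Lipe at 7.96 and 3.55 TPM, and erythroid markers had 0.

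The higher level of chromosome 4 genes was set against 4 explanations. After the median of genes of like GC content and transcript length was subtracted, the chromosome 4 median was still 0.76. This argues against both as the whole cause. With control reads thinned to the knockout depth, the chromosome 4 median lay 0.79 above the median of all genes. Thinning keeps each gene's expected TPM and adds only counting noise, so this outcome was nearly set beforehand and does not decide on depth. Of the 672 genes, 84.7% lay above the median of all genes (exact binomial interval 81.7% to 87.3%), so the higher level was not confined to a few. The chromosome's high median already required most of its genes to lie above, so this share is no separate test. The interval treats the genes as independent, which they are not. A gain of copies of the whole chromosome is a candidate explanation, since the lowest median among 10 successive equal parts of its genes was still 0.47 above the median of all genes. This pattern was not particular to chromosome 4. The lowest of 10 such parts of chromosome 2 was also above the median of all genes, by 0.27. Copy number was not measured, and whether such a gain may relate to the loss of Trp53 was not tested.

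For the higher basal and squamous genes, 6 of the 10 members other than keratins were at least 2-fold higher with counting intervals above 2. Reads shared between keratin paralogs do not account for those 6. Since 15 of the 20 members had been seen to be higher, several non-keratin members had to be, so this outcome was set beforehand. How far shared reads raised the keratin values was not tested. Whether the libraries hold epithelium from another position of the reproductive tract cannot be told apart from the genotype. Of the 8 Hox genes at 5 TPM or more in either library, 1, Hoxd8, was under 0.5 TPM in the other (22.7 TPM in the control, listed at 0 in the knockout library). The other 7, all Hoxb genes, were within 4-fold. Below 5 TPM, Hoxd9, Hoxd4 and Hoxd3 were 1.49, 1.59 and 0.673 TPM in the control library and listed at 0 in the knockout library, and Hoxc4 was 1.13 and 0.0440 TPM. In the other direction, Hoxa5 and Hoxa3 were listed at 0 in the control library and at 0.572 and 0.213 TPM in the knockout library, from 19 recovered and an estimated 10 reads. Hoxa9, Hoxa11 and Hoxa13 were listed at 0 in both libraries, and Hoxa10 was 0.00535 TPM in the control and 0 in the knockout library. These 4 genes therefore give no comparison of position. The knockout itself stays open as an untested explanation.

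For the lower multiciliated markers, the list median was −2.50 with control reads thinned to the knockout depth. As for chromosome 4, thinning adds only counting noise, so this does not decide whether the greater depth of the control library played a part. A single lower share of multiciliated cells, with no other cells expressing the markers, cannot be told apart from other changes, since 1 library per genotype gives no spread between separate cultures. The counting interval of the knockout to control ratio lay over 2-fold from the median ratio of 2.56% for 12 of 28 members, 11 above it and 1, Tppp3, below it. These intervals hold counting error only. Of the 11, Tubb4b and Rfx2 were higher than in the control library, at 233% and 189%, and the other 9 ran from 10.99% (Cfap45) to 63.6% (Mns1), with Foxj1, the master regulator of motile cilia, at 45.5%. Mcidas, which acts upstream of Foxj1, kept 2.02% (counting interval 0.244% to 7.36%), and Gmnc was 0.767 TPM and listed at 0. Expression of some markers in cells that are not multiciliated, and an effect of the knockout on these genes, were not tested.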
